A study of Mus musculus with 6 samples.

How the data were processed

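The series holds 6 Affymetrix mouse arrays of total RNA from white adipose tissue, 3 from wild-type mice and 3 from mice homozygous for a Ksr2 knockout. The design text states that the RNA of each mouse went onto 1 chip, so each array was treated as 1 animal. The labels' characteristics describe all animals as C57Bl6 females aged 6 months. The fat depot and the part of Ksr2 that was deleted are not given in the sources used here. Replicates were numbered in accession order and the labels hold no shared replicate numbers, so no arrays were paired. The animal numbers in the labels fall into a higher-numbered series (wild type 1 and 2, knockout 1 and 2) and a lower-numbered series (wild type 3 and knockout 3), and this series was used as a block in an alternative fit.

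The table analysed was the series' value table. Its values are RMA intensity values that the authors deposited on a linear scale, with the method taken from the submitters' processing notes, which give no RMA version, and the linear scale from the values themselves, whose medians per array were 22.4 to 24.2 and whose maxima were 14273 to 16422. The design written beforehand had assumed log2 values, so log2 was taken of every deposited intensity before the first fit, with no pseudocount because the lowest value was 2.96. RMA summarises the probes of a probe set over all arrays together and normalizes the arrays to 1 common distribution, so the arrays are not independent of each other at that step. The table held 45101 probe sets and no columns of other series. Of these, 64 were controls, 34945 had exactly 1 gene symbol, 932 had several and 9160 had no gene listed in the platform annotation used. Symbols were updated through gene identifiers to the RefSeq genes of GRCm38.p6, which matched 34754 of the single-gene probe sets. That assembly served for names and for the order of neighbouring genes.

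Each gene was represented by 1 probe set, the single-gene probe set with the highest mean over the 6 arrays, which left 18193 genes and no filter on dim genes. Knockout and wild type were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, prior degrees of freedom 3.06), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors are those of the moderated fit. The number of arrays limits the precision, with a median standard error of 0.22 log2 for the difference of a gene.

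Gene lists were tested by preranked gene set enrichment analysis (fgsea 1.28.0, simple permutation, 100000 gene permutations, weight 1, at least 5 measured members) on the moderated statistics of the limma fit, the method named in the design text of the series, and adjusted over 58 lists. Of these, 36 were pathways or functional groups and 22 were markers of cell types that the tissue could hold. Permuting genes treats genes as independent. For that reason camera with a preset correlation of 0.01, camera with a correlation estimated for each list, and fry were run beside it. A list's score on an array is the mean log2 intensity of its measured members, and scores of the groups were compared by a two-sided exact permutation test, which with 3 against 3 arrays cannot go below 0.1. Members were also adjusted over each list alone. The lists share members, and the number of members held by another list is given where it is large.

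The comparison, the lists, the genes named and most alternatives were fixed before the data were examined. The genes named are Ksr2, then up to 12 genes in each direction whose knockout and wild-type values did not overlap and whose higher group mean reached the median of all gene means, taken by size among genes past the threshold and, where fewer than 12 passed, by the smallest unadjusted p, without clone-type symbols. To these came the 4 members with the smallest unadjusted p of each list called and 19 genes fixed in advance, of which 17 were measured by a single-gene probe set. In all 130 genes were named by this rule, of which 66 had more than 1 probe set. Another probe set had the opposite sign in 14 of them, in 0 by more than 0.5 log2. Among these 14 were Atp6v0a1, Cldn3, Ctsa, Etv5, Ighm, Laptm5, Mrpl15, Mrps15, Nrip1, Pck1, Prkaa2, Spry4 and Tgfb1.

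The procedure was tested on simulated data with the spread of the real comparison of 18193 genes. Of 100 genes each changed 2-fold and 4-fold, 18% and 67% were recovered, with 2 false calls, and 3 of 3 shifted lists and 0 unshifted lists were called. With no change simulated, 0 genes and 0 lists were called. The simulated noise was independent between genes, whereas in the real data the correlation estimated for the cell cycle list, for example, was 0.73. The simulation therefore cannot show how often lists are called falsely when their genes are correlated. Alternatives were a filter at the median mean, the mean of all probe sets of a gene, a fit of every probe set, renewed quantile normalization, centring on each array's median, eBayes with trend and robust settings, array weights, the animal number series as a block, a floor at the 20th percentile, leaving out each array in turn, and 2 other ranking statistics for the lists. A covariate for RNA quality (the log2 difference between the 3' and 5' Gapdh control probe sets) and a fit of the higher-numbered series alone were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.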

Results

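Gene expression was measured in white adipose tissue of 6 adult female mice, 3 wild type and 3 lacking Ksr2. KSR2, kinase suppressor of Ras 2, is a scaffold protein of the Raf-MEK-ERK cascade. The RNA of each mouse was hybridized to 1 array, and the question put to the series was which sets of genes differ between the genotypes. Median linear intensities were 22.4 to 24.2 over the 6 arrays, and Pearson correlations between arrays, taken across genes, ran from 0.955 to 0.988. The first principal component held 47.0% of the variance and the second 30.9%. On the first, wild types 1 to 3 scored −22.9, −37.1 and −29.9, knockouts 1 and 2 scored 52.9 and 45.9, and knockout 3 scored −8.99. The second did not separate the genotypes, with wild type 1 at 53.6, knockout 1 at 23.6 and the other arrays between −26.2 and −7.93. Knockout 3 correlated with wild type 3 at 0.988, and with knockouts 1 and 2 at 0.970 and 0.977. Wild type 3 and knockout 3 belong to a lower-numbered series of animals and the other arrays to a higher-numbered one. The 3' minus 5' log2 difference of the Gapdh control probe sets, a measure of RNA integrity, was 4.18 in wild type 3 and between 0.07 and 1.46 on the other arrays.

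**Figure D1:**
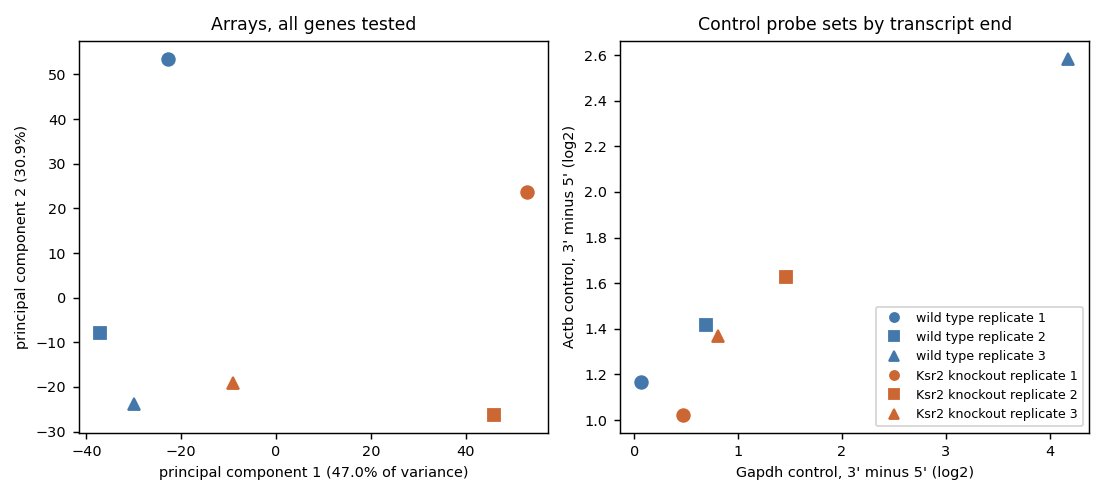
Left, scores of the 6 arrays on the first and second principal components of all genes tested (log2 units, percent of variance on the axes), and right, the 3' minus 5' log2 difference of the Gapdh (x axis) and Actb (y axis) control probe sets, with genotype by colour and replicate by marker. Knockout 3 scores −8.99 on the first component, between the wild types (−37.1 to −22.9) and the other knockouts (45.9 and 52.9), and wild type 3 has the highest Gapdh difference (4.18).

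The Ksr2 probe set read a low signal on every array. Log2 intensities were 4.7, 4.0 and 4.5 in wild types 1 to 3 and 4.5, 4.3 and 4.3 in knockouts 1 to 3, a difference of −0.08 (SE 0.21, limma adjusted p = 0.935). Whether these probes lie within the deleted part of the gene is not given in the sources used here, so the values do not check the genotype labels. Ksr1, the related scaffold, was 6.81 in wild type and 6.77 in knockout (difference −0.04, SE 0.29, adjusted p = 0.983 by limma).

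In knockout fat, gene set enrichment analysis called the lists of macrophage markers, lipid-associated macrophage markers, lysosome, matrix, cell cycle and genes raised in expanding or obese fat higher (adjusted p = 0.528 to 0.540 with an estimated correlation). Knockout 3 moved less than knockouts 1 and 2, with a macrophage score 0.19 above the wild-type mean against 1.34 and 1.54, and a cell cycle score 0.28 above it against 1.46 and 1.83. Oxidative phosphorylation, branched-chain amino acid catabolism and de novo lipogenesis were called lower (adjusted p = 0.528 to 0.631 with an estimated correlation), and lipogenesis shifted the other way, by 0.36, in the lower-numbered pair. There knockout 3 lay −0.26 and wild type 3 −0.61 from the wild-type mean of the lipogenesis score. Of the 58 gene lists, 25 were called by gene set enrichment analysis, 12 higher and 13 lower, and 0 by camera with an estimated correlation or by fry, which gave 1 and 10 lists at an unadjusted p under 0.05. At the level of single genes, 1 of 18193 passed limma at an adjusted p under 0.05. That gene, Il13ra2, which encodes a decoy receptor for interleukin 13, rose 4.46-fold, from 5.16 ± 0.11 to 7.31 ± 0.15 log2 (SD, n = 3 each).

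Il13ra2 was higher by 2.16 log2 (SE 0.16, limma adjusted p = 0.0465), with 2.24 within the higher-numbered series and 2.00 within the lower-numbered pair. With the series as a block its adjusted p was 0.0680 by limma. The call was lost without wild type 1 (adjusted p = 0.190), wild type 2 (0.420), knockout 1 (0.192) or knockout 2 (0.246), and the adjusted p over all 16 alternatives ran from 0.00494 to 0.420. Without knockout 3 it was 0.00494. At an unadjusted limma p under 0.05 there were 2199 genes, 1221 higher and 978 lower, where chance gives 910 on average. Genes are correlated, and a split of the arrays that mixed the genotypes gave 2656, so the excess is not tied to genotype. The 2 groups did not overlap in 2962 genes, or 16.3%, where chance gives 10%, also an average without a spread. Another count, at an adjusted p under 0.1, gave 10 genes, 7 higher and 3 lower. The count past the threshold was 0 without wild type 1, wild type 2, knockout 1 or knockout 2, 9 without wild type 3 and 816 without knockout 3, 574 of them higher and 242 lower. With every array centred on its median gene the count was 16, 10 higher and 6 lower, and with quantile normalization repeated it was 2, both higher. With the animal number series as a block, 0 genes passed limma and 2361 had an unadjusted p under 0.05.

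The other 11 genes named for the best supported higher values did not pass limma, with adjusted p between 0.0876 and 0.152. Tph2, the neuronal form of tryptophan hydroxylase, measured 3.08 ± 0.26 in wild type, near the 20th percentile of all values (2.93), and 8.98 ± 1.34 in knockout, a difference of 5.90 log2 (SE 0.61) that was 6.74 within the higher-numbered series and 4.23 within the lower-numbered pair. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, measured 6.37 ± 0.53 and 10.62 ± 0.86, an 18.9-fold difference. The oxytocin receptor gene Oxtr measured 7.17 ± 0.79 and 10.56 ± 0.01, a 10.5-fold difference. Ccl7, a monocyte-attracting chemokine, measured 5.23 ± 0.25 and 7.35 ± 0.29 (limma adjusted p = 0.0876). The matricellular gene Ccn5 differed by 2.28 log2 (SE 0.30) and Shroom2, which acts on the actin cytoskeleton, by 1.83 (SE 0.23). Differences were 1.53 for Atp6v0a1, a subunit of the proton pump that acidifies lysosomes, 1.52 for the phosphodiesterase Pde2a, 1.65 for Septin9, 1.78 for Dock8 and 1.83 for the elastase Cela1.

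Among the 12 genes named for the best supported lower values, limma adjusted p ran from 0.0894 to 0.193. Acsm3, a medium-chain acyl-CoA synthetase of mitochondria, measured 7.95 ± 0.44 in wild type and 3.78 ± 0.91 in knockout, 18.0-fold lower. Cyp2f2, a cytochrome P450, measured 8.22 ± 0.69 and 4.13 ± 0.93, 17.0-fold lower. The pantetheinase genes Vnn3 and Vnn1 differed by −2.47 (SE 0.31) and −1.06 (SE 0.17) log2. Fam13a differed by −2.42 (SE 0.30), and Tst, the mitochondrial thiosulfate sulfurtransferase, by −2.15 (SE 0.25). Smaller differences were measured for Dennd2d (−1.62), Nabp1 (−1.53), Gulp1 (−1.34), the carbonic anhydrase Car13 (−1.34), Adamtsl1 (−1.16) and the transporter Abca8a (−1.04). Of the 130 genes named by the rule, 69 passed limma without knockout 3 that did not pass with it, among them Tph2 (6.66 log2, adjusted p = 0.000877) and Acsm3 (−4.69, adjusted p = 0.00185). For Tph2 the adjusted p over the 16 alternatives ran from 0.000877 to 0.548.

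**Figure D2:**
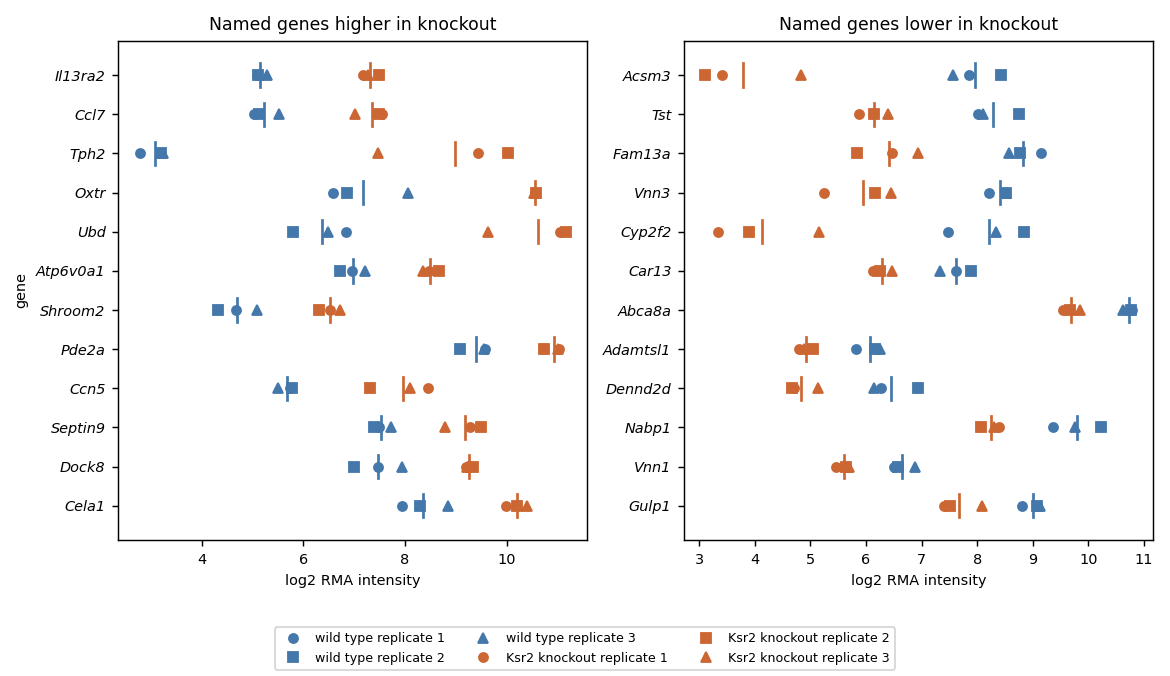
Log2 RMA intensity (x axis) of the 12 genes named for higher and the 12 named for lower values in knockout (y axis), 1 point per array and vertical ticks at the group means. The genes were chosen for groups that do not overlap, and Il13ra2 (5.16 against 7.31) was the one past the threshold.

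Gene set enrichment analysis called 25 lists, at adjusted p from 9.61e-05, the smallest reached with 100000 gene permutations, to 0.0488. Camera with a preset correlation called 23, of which 21 were among the 25. With a correlation estimated for each list camera called 0, at a lowest adjusted p of 0.528. No list member passed limma over all genes. The exact permutation test on list scores gave p = 0.1, the smallest possible, for 11 of the 25. Leaving out single arrays gave 18 to 25 lists, and the lower ones numbered 8 rather than 13 without wild type 2 or without knockout 1. Because each animal number series holds as many wild types as knockouts, a block for the series leaves each list's shift as it is. With it 21 lists were called, and the calls of lipolysis, the Raf-MEK-ERK cascade, complement and adipocyte markers were lost.

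The 75 measured genes of oxidative phosphorylation encode subunits of the respiratory chain and ATP synthase, and 74 of them were lower in knockout. The list fell by gene set enrichment analysis (normalized enrichment score −2.94, adjusted p = 9.61e-05, and adjusted p = 0.585 with an estimated correlation). Its score was 11.18 ± 0.21 in wild type and 10.68 ± 0.33 in knockout. The median difference of its members was −0.48 log2, and the list shifted by −0.60 within the higher-numbered series and −0.28 within the lower-numbered pair. Members past limma numbered 0 over all genes and 0 adjusted over the list alone, with 28 lower and 0 higher at an unadjusted p under 0.05. Cox8b (−1.73, SE 0.41), Cyc1 (−0.80, SE 0.22), Ndufa4 (−0.70, SE 0.19) and Cox6c (−0.48, SE 0.14) had the smallest p.

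All 21 genes of branched-chain amino acid catabolism, which break down leucine, isoleucine and valine in mitochondria, were lower. The list's score was 9.78 ± 0.26 in wild type and 8.88 ± 0.46 in knockout, and it fell at adjusted p = 9.61e-05 by gene set enrichment analysis (adjusted p = 0.528 with an estimated correlation). It shifted by −1.12 within the higher-numbered series and −0.45 within the lower-numbered pair. Passing limma were 13 members adjusted over the list alone, all lower, and 0 over all genes. Among them were Aldh6a1 (−1.22, SE 0.23), the phosphatase Ppm1k that activates the branched-chain ketoacid dehydrogenase (−0.86, SE 0.17), Acadsb (−1.18, SE 0.24) and the mitochondrial aminotransferase Bcat2 (−1.21, SE 0.29). Knockout 3 lay −0.42 from the wild-type mean of this score, against −1.34 and −0.94 for knockouts 1 and 2.

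The tricarboxylic acid cycle list fell likewise, with all 21 members lower and a median of −0.56 (adjusted p = 9.61e-05 by gene set enrichment analysis, adjusted p = 0.575 with an estimated correlation). Its shift was −0.80 in the higher-numbered series and −0.24 in the lower-numbered pair, and Suclg2, Pdha1 (−0.98, SE 0.24), Pdhb (−1.11, SE 0.31) and Idh3b (−0.72, SE 0.21) led it. Of the 44 mitochondrial ribosome genes 42 were lower, with a median of −0.26, Mrps16 at −0.62 (SE 0.20) and Mrps15 at −0.91 (SE 0.35, and −1.16 to −0.57 with 1 array left out). That list fell at adjusted p = 0.000163 by gene set enrichment analysis (adjusted p = 0.758 with an estimated correlation), by −0.42 and −0.10 within the 2 series. The 23 peroxisome genes, 21 of them lower, fell at adjusted p = 0.000163 by gene set enrichment analysis (adjusted p = 0.600 with an estimated correlation), by −0.57 and −0.11, with Scp2 at −0.56 (SE 0.16), the fatty acid transporter Abcd2 at −0.91 (SE 0.26), Hacl1 at −0.90 and Phyh at −0.98 (−1.31 to −0.64 with 1 array left out). In these 3 lists limma passed 0 members over all genes and 0 adjusted over the list alone, with 12, 4 and 5 members lower at an unadjusted p under 0.05.

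Fatty acid beta-oxidation genes fell at adjusted p = 0.00716 by gene set enrichment analysis (adjusted p = 0.708 with an estimated correlation), with 19 of 20 lower and a median of −0.39. The exception was Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, at 1.24 higher (SE 0.26), the 1 member past limma adjusted over the list alone, with 0 over all genes. Echs1 (−1.09, SE 0.32), Ehhadh (−1.04, SE 0.34) and Acot2 (−0.61, SE 0.21) followed. The call was lost without wild type 2 (adjusted p = 0.0935) or knockout 1 (adjusted p = 0.0710), with a range of 0.000343 to 0.708 over 21 alternatives. Regulators of mitochondrial biogenesis fell at adjusted p = 0.0275 by gene set enrichment analysis (adjusted p = 0.631 with an estimated correlation), 11 of 14 members lower. Ppargc1a, the coactivator PGC-1α, measured 5.29 ± 0.52 and 3.65 ± 0.26 (difference −1.64, SE 0.29), the 1 member past limma adjusted over the list alone, with 0 over all genes. Tfam differed by −0.32, Nrip1 by −1.01 (−1.43 to −0.66 with 1 array left out, and 0.01 within the lower-numbered pair) and Sirt1 by −0.42 (−0.62 to −0.27 with 1 array left out). This call was lost without wild type 2 (adjusted p = 0.0935) or knockout 1 (adjusted p = 0.188), with a range of 0.00182 to 0.631 over the alternatives. The shifts within the higher-numbered series and the lower-numbered pair were −0.50 and −0.17 for beta-oxidation and −0.52 and −0.06 for the regulators.

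De novo lipogenesis fell by gene set enrichment analysis (adjusted p = 9.61e-05, and adjusted p = 0.631 with an estimated correlation), with 17 of 20 members lower and a median of −0.75. The 4 arrays of the higher-numbered series gave a shift of −1.58 and the lower-numbered pair one of 0.36 the other way. In that pair both arrays lay below the wild-type mean, knockout 3 by −0.26 and wild type 3, the array with the Gapdh difference of 4.18, by −0.61. Limma passed 0 members over all genes and 0 adjusted over the list alone, with 8 lower at an unadjusted p under 0.05. The acetyl-CoA carboxylase Acacb, the 76th nearest gene to Ksr2 on its chromosome, differed by −2.03 (SE 0.48), Elovl6 by −2.89 (SE 0.96) and Thrsp by −1.86 (SE 0.60), with Elovl6 at 0.61 and Thrsp at 0.05 the other way within the lower-numbered pair. Fatty acid synthase, Fasn, measured 12.71 ± 0.78 and 11.64 ± 0.81 (limma adjusted p = 0.470), with −1.97 and 0.75 within the 2 series, and Scd1 differed by −0.47 (SE 0.20, limma adjusted p = 0.406). Triglyceride synthesis genes were not called (normalized enrichment score −1.33, adjusted p = 0.236).

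Genes of lipolysis and the lipid droplet fell at adjusted p = 0.0271 by gene set enrichment analysis (adjusted p = 0.777 with an estimated correlation), 11 of 15 lower. Adjusted over the list alone limma passed 3 lower and 1 higher, and 0 over all genes. Cidea, a lipid droplet protein, differed by −3.07 (SE 0.70), Hcar1 by −1.26 (SE 0.32) and the phosphodiesterase Pde3b by −0.89 (SE 0.18), while the droplet coat gene Plin2 was 1.00 higher (SE 0.20). The call was lost without wild type 2 (adjusted p = 0.103), knockout 1 (0.104) or knockout 2 (0.0644), with a range of 0.00221 to 0.777 over the alternatives. Adipogenic transcription factors fell at adjusted p = 0.0389 by gene set enrichment analysis (adjusted p = 0.777 with an estimated correlation), 17 of 21 lower, with Klf15 at −1.03 (SE 0.33), Ebf2 at −0.79 (−1.04 to −0.50 with 1 array left out), Srebf1 at −0.86 and Tle3 at 0.47. That call was lost without wild type 2 (adjusted p = 0.144), wild type 3 (0.116), knockout 1 (0.188) or knockout 2 (0.0560), or with the Gapdh 3' minus 5' difference as a covariate (0.0722), with a range of 0.00256 to 0.777. Limma passed 0 of the factors over all genes and 0 adjusted over the list alone, with 3 lower and 1 higher at an unadjusted p under 0.05. Shifts within the 2 series were −0.75 and −0.03 for lipolysis and −0.49 and −0.15 for the factors. Pparg measured 10.77 and 9.97 (difference −0.80, SE 0.40, and −1.13 to −0.48 with 1 array left out).

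Adipocyte markers, 9 of whose 13 measured members stand on other lists, fell at adjusted p = 0.0412 by gene set enrichment analysis (adjusted p = 0.818 with an estimated correlation). Limma passed 0 of them over all genes and 0 adjusted over the list alone, with 4 lower and 1 higher at an unadjusted p under 0.05. Knockout 3 lay 0.34 above the wild-type mean of their score and knockouts 1 and 2 at −0.79 and −0.42, and within the series the shift was −0.48 and 0.09. The call was lost without wild type 1 (adjusted p = 0.142), wild type 2 (0.100), wild type 3 (0.375), knockout 1 (0.301) or knockout 2 (0.107), or with the Gapdh covariate (0.345), with a range of 0.000497 to 0.818. Pck1, which supplies glycerol for triglyceride, differed by −2.05 (SE 0.63) and Acvr1c by −0.56 (SE 0.23). Among the hormones of adipocytes, resistin (Retn) measured 13.37 ± 0.05 and 12.14 ± 0.92, adiponectin (Adipoq) 13.52 ± 0.06 and 13.02 ± 0.35, and leptin (Lep) 10.77 ± 1.21 and 12.22 ± 0.36, with limma adjusted p of 0.325, 0.400 and 0.380. The Lep difference of 1.45 was 0.77 without wild type 1. The insulin-responsive glucose transporter Slc2a4 measured 9.49 ± 0.34 and 8.09 ± 1.17 (limma adjusted p = 0.380), with −2.25 and 0.30 within the 2 series. Ucp1 differed by −0.07 (SE 1.01).

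Macrophage markers rose by gene set enrichment analysis (adjusted p = 9.61e-05, and adjusted p = 0.540 with an estimated correlation), with 19 of 20 higher and a score of 8.70 ± 0.12 in wild type and 9.73 ± 0.73 in knockout. Knockouts 1 and 2 lay 1.34 and 1.54 above the wild-type mean and knockout 3 lay 0.19 above it. Limma passed 6 members adjusted over the list alone and 0 over all genes. Cd68 measured 7.72 ± 0.21 and 10.19 ± 1.17, the scavenger receptor Msr1 differed by 2.11 (SE 0.58), Laptm5 by 1.37 (SE 0.41) and Ms4a7 by 2.10 (SE 0.64). Adgre1, an adhesion receptor of mature macrophages, measured 8.52 ± 0.33 and 10.01 ± 1.09 (limma adjusted p = 0.323), with 2.26 within the higher-numbered series and −0.04 within the lower-numbered pair. Markers of lipid-associated macrophages, 12 of 14 shared with other lists, rose at adjusted p = 9.61e-05 by gene set enrichment analysis (adjusted p = 0.528 with an estimated correlation), from a score of 8.75 ± 0.08 to 10.70 ± 0.97. Limma passed 10 of the 14 adjusted over the list alone and 0 over all genes, and the shift was 2.55 and 0.74 within the 2 series. The macrophage elastase Mmp12 measured 5.11 ± 0.32 and 11.17 ± 1.93, a difference of 6.07 log2 (SE 0.86, and 5.46 to 7.18 with 1 array left out) that was 7.36 within the higher-numbered series and 3.48 within the lower-numbered pair. Itgax (CD11c) differed by 3.30 (SE 0.61), Trem2 by 2.94 (SE 0.69) and Lgals3 by 1.85 (SE 0.36).

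The list of genes raised in expanding or obese fat, 15 of whose 20 members stand on other lists, rose by gene set enrichment analysis (adjusted p = 9.61e-05, and adjusted p = 0.528 with an estimated correlation). Its score was 7.78 ± 0.22 in wild type and 9.94 ± 0.77 in knockout, higher by 2.73 in the higher-numbered series and 1.04 in the lower-numbered pair. Limma passed 13 members adjusted over the list alone, all higher, and 0 over all genes. Mest, a marker of fat expansion, measured 8.98 ± 0.44 and 11.08 ± 0.43, and the monocyte chemokine Ccl2 measured 6.70 ± 0.35 and 9.16 ± 0.67. Inflammatory signalling rose at adjusted p = 9.61e-05 by gene set enrichment analysis (adjusted p = 0.528 with an estimated correlation), 22 of 26 higher, by 0.98 and 0.19 within the 2 series. Passing limma were 3 members adjusted over the list alone and 0 over all genes. The acute-phase gene Saa3 differed by 2.76 (SE 0.66) and the chemokine Cxcl2 by 2.64 (SE 0.77). Lysosomal genes rose in the same test (adjusted p = 9.61e-05 by gene set enrichment analysis, adjusted p = 0.528 with an estimated correlation), all 27 higher with a median of 0.76, and by 1.38 and 0.23 within the 2 series. Adjusted over the list alone 14 passed limma, and 0 over all genes, with the cholesterol transporter Npc1 at 1.21 (SE 0.28), cathepsin S (Ctss) at 1.69 (SE 0.39) and Ctsa at 1.01 (SE 0.26). The 1 other probe set of Ctsa had the opposite sign, by 0.5 log2 or less.

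Complement genes rose at adjusted p = 0.0488 by gene set enrichment analysis (adjusted p = 0.528 with an estimated correlation), 9 of 12 higher, by 0.82 and 0.17 within the 2 series. Adjusted over the list alone limma passed 5 higher and 2 lower, and 0 over all genes. The 3 chains of C1q, made by macrophages, were higher (C1qa 1.43, C1qb 1.12, C1qc 1.07) and the protease Masp1 was lower (−0.91, SE 0.26). The call was lost without wild type 1 (adjusted p = 0.119), wild type 3 (0.0604), knockout 1 (0.0811), knockout 2 (0.0753) or knockout 3 (0.0831), with a range of 0.0108 to 0.528 over the alternatives. B cell markers rose at adjusted p = 0.0382 by gene set enrichment analysis (adjusted p = 0.758 with an estimated correlation), 11 of 15 higher, with Ighm at 1.10 (SE 0.30), Cd72 at 2.10 (SE 0.75), Cd79b at 0.61 (SE 0.31) and Cd22 at 0.82 (SE 0.50). With 1 array left out, Cd79b ran from 0.30 to 0.93 and Cd22 from 0.35 to 1.37. Within the 2 series they shifted by 0.33 and 0.72, and wild type 1 lay 0.73 above the wild-type mean where knockouts 1 to 3 lay 0.65, 0.49 and 0.24 above it. Limma passed 0 of them over all genes and 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05. The B cell call was lost without wild type 2 (adjusted p = 0.183), wild type 3 (0.548), knockout 1 (0.223), knockout 2 (0.0644) or knockout 3 (0.0831), or with the Gapdh covariate (0.178), with a range of 0.000134 to 0.758.

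Extracellular matrix and fibrosis genes rose by gene set enrichment analysis (adjusted p = 9.61e-05, and adjusted p = 0.528 with an estimated correlation), 30 of 32 higher with a median of 0.64, by 0.90 and 0.21 within the 2 series. Limma passed 8 adjusted over the list alone and 0 over all genes. Transforming growth factor beta 1 (Tgfb1) measured 6.02 ± 0.33 and 7.54 ± 0.19, the protease inhibitor Timp1 differed by 2.95 (SE 0.64), the basement membrane collagen Col4a2 by 0.98 (SE 0.21) and the proteoglycan Bgn by 0.86 (SE 0.19). The 1 other probe set of Tgfb1 had the opposite sign, by 0.5 log2 or less. Cell cycle genes rose in the same way (adjusted p = 9.61e-05 by gene set enrichment analysis, adjusted p = 0.528 with an estimated correlation), with 29 of 30 higher, a median of 1.23 and a score of 5.26 ± 0.11 in wild type and 6.45 ± 0.81 in knockout. Adjusted over the list alone 17 passed limma, and 0 over all genes, among them Ube2c (1.29, SE 0.27), the replication helicase genes Mcm5 (1.67, SE 0.40) and Mcm3 (1.17, SE 0.30), and Birc5 (2.46, SE 0.65). Within the higher-numbered series the cell cycle shift was 1.69 and within the lower-numbered pair 0.19.

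Downstream of the cascade that KSR proteins scaffold, ERK output and feedback genes rose by gene set enrichment analysis (adjusted p = 9.61e-05, and adjusted p = 0.528 with an estimated correlation), 18 of 20 higher with a median of 0.32. Within the 2 series they shifted by 0.55 and 0.02. Limma passed 0 over all genes and 0 adjusted over the list alone, with 4 higher at an unadjusted p under 0.05, namely Etv5 (1.07, SE 0.25), Fosl1 (0.82, SE 0.23), Ccnd1 (0.87, SE 0.27) and Spry4 (0.63, SE 0.20). Of the 3 other probe sets of Spry4, 2 had the opposite sign, as had 1 of the 2 others of Etv5, each by 0.5 log2 or less. Immediate early genes, which also respond to tissue handling, rose at adjusted p = 9.61e-05 by gene set enrichment analysis (adjusted p = 0.528 with an estimated correlation), 23 of 26 higher, by 1.05 in the higher-numbered series and −0.10 in the lower-numbered pair. Junb differed by 1.43 (SE 0.33), Maff by 0.98 (SE 0.22), Egr2 by 2.67 (SE 0.74) and Atf3 by 2.67 (SE 0.77), and 2 members passed limma adjusted over the list alone, with 0 over all genes. The members of the Raf-MEK-ERK cascade itself were called higher at adjusted p = 0.0488 by gene set enrichment analysis (adjusted p = 0.758 with an estimated correlation) with a median of 0.05, 14 of 22 above 0, and shifts of 0.16 and 0.04. This last call was kept in 0 of 19 alternatives other than camera with an estimated correlation and fry. Leaving out wild types 1 to 3 gave an adjusted p of 0.747, 0.0528 and 0.0692 and leaving out knockouts 1 to 3 gave 0.112, 0.255 and 0.408, and the Gapdh covariate gave 0.0722, within a range of 0.0528 to 0.758. Its leading members were Ywhaz (0.44, SE 0.17), Nras (0.78, or 0.39 to 1.00 with 1 array left out), Cdc37 (0.36, or 0.21 to 0.52) and Grb2 (0.37, or 0.16 to 0.53), with 0 past limma over all genes, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Subunits and regulators of AMPK, a kinase with which KSR proteins can associate, were not called (adjusted p = 0.561 by gene set enrichment analysis), with a negative enrichment score of −0.98 and a median of 0.03 above 0. The catalytic subunit genes did not pass limma, with Prkaa1 at −0.80 (SE 0.25, limma adjusted p = 0.301) and Prkaa2 at −0.52 (SE 0.27, limma adjusted p = 0.523). Prkaa2 was −0.87 and 0.19 within the 2 series and −0.27 at its smallest with 1 array left out.

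**Figure D3:**
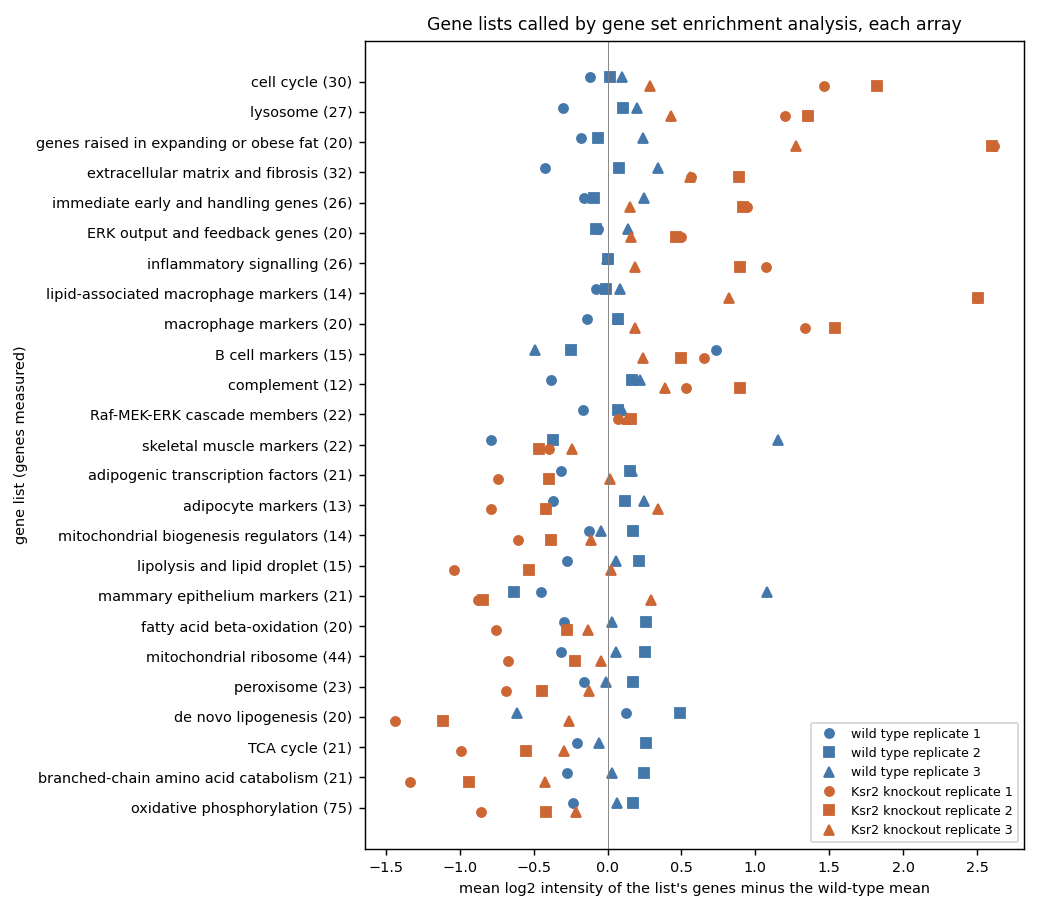
Score of each of the 25 called lists (y axis, with the number of genes measured) on every array, as the mean log2 intensity of its genes minus the wild-type mean (x axis), with genotype by colour and replicate by marker. For lipid-associated macrophage markers knockouts 1 and 2 lie at 2.50 and 2.51 and knockout 3 at 0.82, and for skeletal muscle markers wild type 3 lies at 1.15.

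Of 2 tissues that can lie beside a fat pad, marker lists were called lower, and neither call was kept with the Gapdh 3' minus 5' difference as a covariate (adjusted p = 0.371 for skeletal muscle and 0.0779 for mammary epithelium). That difference was highest, at 4.18, in wild type 3, the array with the highest score on both lists. Losing the calls with the covariate therefore cannot separate RNA quality from the tissue content of that array. Skeletal muscle markers fell at adjusted p = 0.0412 by gene set enrichment analysis (adjusted p = 0.818 with an estimated correlation), 19 of 22 lower, with Myl1 at −1.01 (SE 0.29) and Myh7 at −0.43 (SE 0.17). With 1 array left out, Tnnc2 ran from −1.89 to −0.38 and Actn3 from −1.15 to −0.25. Wild type 3 lay 1.15 above the wild-type mean of that score, and the shift was 0.14 within the higher-numbered series and −1.39 within the lower-numbered pair. Without wild type 3 the list turned to a positive score (1.10, adjusted p = 0.464), and the call was also lost without knockout 2 (adjusted p = 0.233) or knockout 3 (0.179), within a range of 0.00170 to 0.818. Mammary epithelium markers fell at adjusted p = 0.0110 by gene set enrichment analysis (adjusted p = 0.777 with an estimated correlation), 16 of 21 lower, with Cldn3 at −0.71 (SE 0.26). With 1 array left out, Elf5 ran from −2.13 to −0.78 and Esr1 from −1.82 to −0.77, and the knockout mean of Csn2 (2.70) lay below the 20th percentile of all values (2.93). Wild type 3 lay 1.08 and knockout 3, with a Gapdh difference of 0.81, lay 0.29 above the wild-type mean. The higher-numbered arrays lay between −0.87 and −0.45 from it, and the shift was −0.32 and −0.79 within the 2 series. That call was lost without wild type 3 (adjusted p = 0.464), knockout 1 (0.0558) or knockout 2 (0.150), within a range of 0.000228 to 0.777. Limma passed 0 members of either list over all genes and 0 adjusted over the list alone, with 2 muscle and 3 mammary markers lower at an unadjusted p under 0.05.

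The other 33 lists were not called by gene set enrichment analysis, with normalized enrichment scores from −1.58 to 1.54. Nearest to the threshold were interferon response (−1.57, adjusted p = 0.0564, and called in 10 of 21 alternatives), brown and beige thermogenic genes (−1.58, adjusted p = 0.0620), lymphatic endothelial markers (−1.50, adjusted p = 0.0941), class II antigen presentation (1.54, adjusted p = 0.0941) and the unfolded protein response (1.47, adjusted p = 0.0997). Adjusted over the list alone limma passed 4 thermogenic genes as lower and 1 as higher, and 0 over all genes. Among adipokines and secreted factors (1.20) it passed 5 higher and 6 lower adjusted over the list alone and 0 over all genes. Enrichment scores were −1.26 for insulin signalling, 1.12 for hypoxia, −1.05 for NRF2 and glutathione, 0.95 for cholesterol synthesis, 0.76 for glycolysis, 1.11 for the proteasome and 1.30 for genes next to Ksr2. Scores and medians differed in sign for fatty acid uptake (1.07 and a median of −0.01), the cytosolic ribosome (0.71 and −0.03) and the circadian clock (−0.89 and 0.03). Among cell markers the scores were 1.08 for fibroblasts, 0.85 for mesothelium, 1.05 for endothelium, 0.98 for mural cells, 1.25 for neutrophils, 1.29 for T cells, 0.49 for natural killer cells, 1.02 for dendritic cells, 1.33 for mast cells and eosinophils, 1.13 for erythroid cells and −1.18 for nerve. Plasma cells (1.42 and −0.13), the female reproductive tract (0.71 and −0.06), pancreas (1.09 and −0.10) and kidney and adrenal (0.85 and −0.11) had positive scores and negative medians.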

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

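The test reported in this part, a limma fit of every probe set, was fixed before its result was seen. The comparison of genes left out 9160 probe sets with no gene listed. Only those of them higher in knockout with no overlap between the groups were ranked. Of these, the probe set with the smallest p drew attention as a signal in data not otherwise analysed. It measured 7.95 log2 in wild type and 9.54 in knockout, a difference of 1.59 (SE 0.19), with 9.74, 9.62 and 9.25 in knockouts 1 to 3 and 7.93, 7.76 and 8.16 in wild types 1 to 3. It did not pass over all probe sets (limma adjusted p = 0.196). The next such probe sets by p differed by 1.65 and 1.76 log2.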

How the results depend on the processing

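The fit with the Gapdh 3' minus 5' covariate and the fit of the higher-numbered series alone were chosen after seeing the data. The counts of genes past limma (1, 1 higher and 0 lower) depended on most settings, and the cause of these changes was not tested. They were 12 (8 higher, 4 lower) without dim genes, 0 (0 higher) with every probe set tested, 2 (2 higher) with quantile normalization repeated, 16 (10 higher, 6 lower) with centred arrays, 10 (7 higher, 3 lower) with trend and robust settings, 16 (9 higher, 7 lower) with array weights, 0 (0 higher) with the animal number series as a block, 0 (0 higher) with the floor at the 20th percentile, 6 (4 higher, 2 lower) with the covariate and 487 (369 higher, 118 lower) with the higher-numbered series alone. Leaving out each array in turn gave 0 to 816, with 0 to 574 higher and 0 to 242 lower. Genes at an unadjusted limma p under 0.05 (2199) numbered 1265 without dim genes, 4544 among all probe sets, where more were tested, and 1169 to 2947 when 1 array was left out. The mean of all probe sets kept the count of 1. For the lists (25, 12 higher and 13 lower by gene set enrichment analysis) the floor left 16, 7 of them lower, camera with an estimated correlation left 0 (0 higher, 0 lower) with 1 at an unadjusted p under 0.05, and fry left 0 (0 higher, 0 lower) with 10. Lower lists numbered 8 to 13 when 1 array was left out. Of the 25 called lists, 15 kept their call in all 19 other settings: oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrial ribosome, peroxisome, lipogenesis, branched-chain amino acids, ERK output, immediate early genes, obese fat, matrix, inflammation, cell cycle, lysosome, macrophages and lipid-associated macrophages. The Raf-MEK-ERK cascade kept it in 0, complement and adipocyte markers in 5 each, skeletal muscle in 9, B cells in 10, adipogenic factors in 11, lipolysis and mammary markers in 12 each, mitochondrial biogenesis in 15 and beta-oxidation in 16. Results that turned in direction were small or varied widely between arrays. The score of skeletal muscle markers (−1.64) was 1.09 in the higher-numbered series alone and −2.01 to 1.10 when 1 array was left out. Ksr2 (−0.08) was 0.027 with array weights and −0.27 to 0.082 with 1 array left out. Ksr1 (−0.04) was 0.084 with the covariate, 0.0077 in the higher-numbered series and −0.32 to 0.18 with 1 array left out, and Ucp1 (−0.07) was 0.54, 0.40 and −0.75 to 1.08. Among the 130 named genes, 69 gained a call without knockout 3, 55 in the higher-numbered series, 11 with array weights, 10 each without dim genes and with centring, 6 with trend and robust settings and 1 each with the covariate and without wild type 3. The 20th percentile of the values was 2.93 log2, so differences of genes near it, such as Tph2 in wild type, rest on signal close to background.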

Other observations

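Tests chosen only after the result was seen are the 3 on knockout 3, the 3 on the share of adipocytes and that on 1500011B03Rik and 2610524H06Rik, and Tbx1, Otop1 and the genes past the threshold without wild type 3 were picked after their values were seen. Thermogenic genes went both ways. Cidea (−3.07, SE 0.70), Ppargc1a (−1.64, SE 0.29), Cox8b (−1.73, SE 0.41) and Tbx1 (−0.63, SE 0.16) were lower and the proton channel gene Otop1 was 1.89 higher (SE 0.29), while Ucp1 measured 4.97 ± 1.99 and 4.89 ± 1.17. Otop1 measured 4.96 ± 0.34 in wild type and 6.84 ± 0.49 in knockout, with no overlap between the groups (limma adjusted p = 0.174). Without wild type 3, limma passed 9 genes. Beside Il13ra2 and Oxtr these were Cdkl4 (4.17), Crtac1 (2.48) and Ddah1 (2.08) on the higher side, and Spink8 (−4.73), H2-Q10 (−4.16), Serpina1f (−4.06) and the prostaglandin synthase gene Ptgs2 (−3.41) on the lower.

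Some markers of other cells differed between arrays of 1 genotype and were also chosen after their values were seen. Mesothelial markers lay 0.86 and 1.15 above the wild-type mean in wild type 3 and knockout 3, the lower-numbered animals, and between −0.75 and −0.28 on the other arrays. Mural and smooth muscle markers did likewise, at 0.34 and 0.67 against −0.44 to −0.05. T cell markers were highest in wild type 1 (0.66) and knockout 1 (0.79), and stood between −0.46 and 0.02 elsewhere. No test of these array differences was run.

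Leaving out knockout 3 raised the number of genes past limma from 1 to 816. A wild-type array under the wrong label is argued against by the list raised in obese fat, chosen afterwards for this test. On it knockout 3 lay 1.28 above the wild-type mean, where the highest wild type lay 0.24 above it. Its scores for lipid-associated macrophages (0.82) and branched-chain genes (−0.42) also lay outside the wild types. Those for oxidative phosphorylation (−0.21), lipogenesis (−0.26) and immediate early genes (0.15) lay within their range, so a wrong label of knockout 3 is not excluded. Degraded RNA is argued against by its Gapdh 3' minus 5' difference of 0.81, below the 1.46 of knockout 2. A shift common to both lower-numbered arrays along the axis between the genotypes is argued against too: on a scale with the mean of 2 wild types at 0 and that of knockouts 1 and 2 at 1, over 500 genes chosen on those 4 arrays, wild type 3 was displaced by 0.15 from 0 and knockout 3 by −0.71 from 1. The test cannot see an effect of the series on the knockout alone. As mesothelial and mural markers were high in both arrays, an effect of the series stays open. A mixed or differently dissected sample and a weaker response of that animal may each account for the smaller shift of knockout 3 and stay open. No biological explanation was tested because the design names none for this array.

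Lists of branched-chain amino acid, oxidative phosphorylation and lipogenic genes and of adipocyte markers were called lower in knockout by gene set enrichment analysis (adjusted p = 0.528, 0.585, 0.631 and 0.818 with an estimated correlation). In the lower-numbered pair lipogenesis and adipocyte markers shifted the other way (0.36 and 0.09). For lipogenesis both arrays of that pair lay below the wild-type mean, wild type 3 (−0.61) further than knockout 3 (−0.26). The adipocyte call was kept in 5 of 21 settings, with an exact permutation p of 0.6 for its score. The branched-chain score fell further than that of adipocyte markers (difference −0.61, SE 0.13), which was not clear for oxidative phosphorylation (−0.20, SE 0.20) and lipogenesis (−0.65, SE 0.43). The markers themselves went both ways, 9 lower and 4 higher, with Pck1 at −2.05 and Lep at 1.45. Their mean is therefore no clean measure of the share of adipocytes. A smaller share as the whole cause stays open for all these lists. With the Gapdh 3' minus 5' difference as a covariate, the branched-chain score kept a shift of −0.87 (SE 0.36), more than 2 standard errors from 0. With only 6 arrays that is a lenient limit, and the covariate rests mainly on wild type 3 (4.18). The covariate alone therefore does not settle unequal RNA quality for the branched-chain genes. Oxidative phosphorylation kept its list call with a shift of −0.46 (SE 0.26) in place of −0.49. That is within 2 standard errors of 0, so the covariate does not settle it there either. The arrays' own values argue against lower RNA quality, as the Gapdh difference measures it, as the cause of either fall. Wild type 3, with a difference of 4.18, lay 0.06 and 0.03 above the wild-type mean of the oxidative phosphorylation and branched-chain scores. Knockout 1, with 0.47, lay −0.86 and −1.34 from it, while wild type 2, with 0.69, lay 0.17 and 0.25 above it. An effect of the genotype within adipocytes was not tested, and the comparison with adipocyte markers was chosen after the results had been seen.

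Alleles of another strain carried along with the knockout could shift genes near Ksr2, but among the 100 genes nearest to Ksr2 on its chromosome, 12 had an unadjusted limma p under 0.05, or 12.0%, against 12.1% of the rest (odds ratio 0.99, interval 0.49 to 1.82, two-sided Fisher's exact test p = 1), which argues against a broad effect. Of the 50 genes with the smallest p, 2 were near Ksr2 where 0.275 are expected (one-sided Fisher's exact test p = 0.0309). They were 1500011B03Rik, at 6.10 ± 0.26 in wild type and 8.44 ± 0.25 in knockout (limma adjusted p = 0.0799), and 2610524H06Rik, at 5.38 ± 0.21 and 6.93 ± 0.40 (limma adjusted p = 0.174). As these are neighbours (52nd and 51st nearest to Ksr2), they are not independent, and linked alleles stay open for them and for Acacb (−2.03 log2), the 76th nearest gene and among the 12. Knockout 3 showed 1.15 of the other knockouts' shift in 1500011B03Rik, but 0.615 in 2610524H06Rik and 0.679 in Acacb, single values without a spread, of which the last 2 go against an allele acting alike in all 3 knockouts without excluding it.

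The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1 gene past limma where the highest other gave 0, so 1 split of the 10, the real one itself, gave as many. For lists it gave 25 and the highest other 27, and 3 splits, the real one included, gave as many or more. For genes at an unadjusted p under 0.05 it gave 2199 and the highest other 2656. There 2 splits, the real one included, gave as many or more. The split of wild type 1 with knockouts 1 and 2 against the rest gave both 27 lists and 2656 genes, and that of wild types 1 and 2 with knockout 3 gave 27 lists and 1015 genes. Both set knockout 3 among wild types, a structure of the samples that the first principal component also shows.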
